A study of Homo sapiens with 15 samples.

How the data were processed

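Poly(A)-selected RNA was sequenced from 15 libraries of K562 cells, a line derived from chronic myelogenous leukaemia that carries erythroid features. The labels name 5 groups of 3 libraries, made by CRISPR interference (a guide directs a catalytically dead Cas9 repressor to a promoter): Control, DHX29-knockdown, GIGYF2-knockdown, 4EHP-knockdown and DHX29/4EHP-knockdown. Libraries were strand-specific (NEBNext Ultra II Directional) and were read on a NextSeq 500. The processing notes name Trim Galore 0.6.10, HISAT2 2.2.1, featureCounts from Subread 2.0.1 and the hg38 genome. The annotation release, the strand setting of the counting and the treatment of reads with several alignments are not given in the sources used here.

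The authors deposited 1 table of raw counts, whole-number reads per gene with no normalization, with 66023 gene identifiers and 1 column per library. A read was present in any library for 42797 of these identifiers. Coordinates, gene types and coding sequences came from GENCODE release 29 on hg38, in which 56927 of the identifiers, holding 92.9% of all reads, were found by their Ensembl number. The table uses older symbols for some genes, so current names are added where they differ (SKIV2L2 is MTREX, PPAP2A is PLPP1, C2orf82 is SNORC, SGK223 is PRAG1, DDX58 is RIGI, LINC00657 is NORAD). Reads of the pseudogene EEF1A1P5 reached 47.9% of those of its parent EEF1A1, so values of genes with close copies are uncertain.

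Library totals ran from 22440448 to 37116583 counts. Genes with too few counts were left out with the filterByExpr function of edgeR 4.0.16 by group in R 4.3.3, which left 21661 tested genes. All 15 libraries were fitted at once with group means, TMM normalization (factors 0.974 to 1.02) and the robust quasi-likelihood test of edgeR, with 10 residual degrees of freedom. The common dispersion was 0.00364, a biological coefficient of variation of 6.04%. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, with no threshold on the fold, and counts of called genes that changed at least 1.5-fold are given beside. Errors of log2 fold changes are standard errors (SE) from this fit, and those of CPM (counts of a gene scaled by library total and TMM factor) are standard deviations (SD) over n = 3 libraries. The labels do not say whether replicates were separate cultures, so every p-value measures only the spread between these samples. Intervals and floors cover counting error only.

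The 9 comparisons were each knockdown against Control, the double knockdown against each single one, GIGYF2- against 4EHP-knockdown, DHX29- against 4EHP-knockdown, and the interaction, (DHX29/4EHP minus DHX29) minus (4EHP minus Control) on the log2 scale. Named genes followed a rule: the targets in every comparison, the 6 highest and 6 lowest fold changes against Control among called genes with a mean of at least 1 CPM and no overlap between the groups (4 and 4 in the other comparisons), up to 4 called members of each list with the largest change, and the tested neighbours of the target loci. Genes of this rule whose call was lost on leaving out 1 library are mostly left out of the text. A few other genes are named with a statement that they were picked after their values were seen. The comparisons, lists, named-gene rule and first alternatives were set before the data were examined.

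The 25 gene lists were the 4EHP-GIGYF complex and its partners, neighbours of the CRISPRi targets, CCR4-NOT and mRNA decay, ribosome collision and quality control, translation initiation factors, cytosolic ribosomal proteins, ATF4 targets of the integrated stress response, the endoplasmic reticulum unfolded protein response, the heat shock response, cholesterol and fatty acid synthesis, immediate early genes, cytokines with AU-rich 3′ UTRs, interferon-stimulated genes, erythroid, megakaryocytic, granulocyte and monocyte, lymphoid, and fibroblast and epithelial genes, S phase and replication, mitosis, hypoxia and glycolysis, snoRNA hosts and related non-coding RNAs, mitochondrially encoded mRNAs, numbered zinc finger genes and replication-dependent histones. Each list was compared with the other tested genes by camera in limma 3.58.1 on voom values with a preset correlation of 0.01, and again with an estimated correlation. Adjusted p-values of camera are over the 25 lists of a comparison.

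GC3 is the share of G or C at the third codon position, taken from the longest annotated coding sequence of each of 12538 tested genes. The GC3 index of a library is the mean log2 CPM (prior count 2) of the 20% of genes with the lowest GC3 minus that of the 20% with the highest, and groups were compared by an exact two-sided permutation test. Effects shared by comparisons with the same controls were set against 20 simulated experiments in which no gene changed.

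The alternatives tried were RLE size factors, no filter on low counts, DESeq2 1.42.0, limma-voom, the libraries of a comparison alone, a replicate block, a fold threshold, leaving out each library in turn, other definitions of the GC3 index, Spearman's rho, genes with at least 10 CPM and the fry test. A smooth offset per library on transcript GC and length, and a fit on replicates 1 and 3 of each group, were added after seeing the data. The tests were tried on simulated data, in which 50 genes each were changed 1.25-, 1.5-, 2- and 4-fold, and 54%, 74%, 94% and 100% of them were called, with 11 false calls. No library was left out. Guide sequences and protein levels were not used here.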

Results

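RNA levels were measured in K562 cells in 5 groups of 3 libraries, to compare the effects of lowering DHX29, GIGYF2 or 4EHP, or DHX29 and 4EHP together. DHX29 is a DExH-box helicase that binds the small ribosomal subunit, 4EHP (gene EIF4E2) is a cap-binding protein that does not engage eIF4G, and GIGYF2 is the scaffold with which 4EHP represses translation. Library totals for replicates 1 to 3 were 30487745, 27529635 and 27496455 counts in Control and 29334456, 25859156 and 22440448 in DHX29-knockdown cells. They were 27763403, 27412388 and 27607299 in GIGYF2-knockdown, 30710203, 33775521 and 37116583 in 4EHP-knockdown, and 32361009, 36604381 and 32321142 in DHX29/4EHP-knockdown cells. In a principal component analysis, the first component (25.1% of the variance) held the Control libraries between -43.5 and -28.6 and every other library between -5.91 and 15.9. Replicate 2 stood apart within its group. The chi-square per degree of freedom between replicates 1 and 3 of a group was 1.80 to 2.84, against 3.19 to 7.66 for pairs with replicate 2 in 4 groups and 24.6 and 23.7 for pairs with replicate 2 of GIGYF2-knockdown.

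Each targeted mRNA was low in the groups whose name carries it. DHX29 (ENSG00000067248.9, hg38 chromosome 5, 55256245 to 55307722) was at 9.10 ± 0.635 CPM (SD, n = 3) in DHX29-knockdown cells against 56.6 ± 4.50 CPM in Control, or 16.1% of Control, and at 15.7% in the double knockdown. GIGYF2 (ENSG00000204120.14, chromosome 2, 232697299 to 232860575) was at 2.87 ± 0.285 CPM against 96.5 ± 1.62 CPM, or 2.97%. EIF4E2 (ENSG00000135930.13, chromosome 2, 232550052 to 232583644) was at 0.849 ± 0.204 CPM in 4EHP-knockdown and 0.714 ± 0.0622 CPM in double-knockdown cells, against 63.9 ± 2.58 CPM, or 1.33% and 1.12%. The log2 fold changes were -2.64 ± 0.068 (SE) for DHX29 (adjusted p = 4.13e-17), -5.07 ± 0.056 for GIGYF2 (adjusted p = 5.02e-25) and -6.22 ± 0.086 for EIF4E2 (adjusted p = 8.03e-23). DHX29 was also 1.27-fold higher in GIGYF2-knockdown (adjusted p = 3.59e-05) and 1.31-fold higher in 4EHP-knockdown cells (adjusted p = 7.55e-06). This rise was not particular to DHX29: in the same groups MTREX was 1.239- and 1.258-fold and PLPP1 1.355- and 1.399-fold higher. EIF4E2 was at 88.3% of Control in DHX29-knockdown cells (adjusted p = 0.00857).

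Genes beside the targets fell with them. MTREX (SKIV2L2), the helicase of the nuclear exosome, starts 38 bp from DHX29 on the opposite strand and was at 44.2% of Control in DHX29-knockdown and 41.9% in double-knockdown cells (log2 fold changes -1.18 ± 0.091 and -1.25 ± 0.091, adjusted p = 6.58e-07 and 2.93e-07). PLPP1 (PPAP2A), a lipid phosphatase that starts 227328 bp from DHX29 and whose 3′ end overlaps that of MTREX, was at 55.6% and 52.3%. TIGD1, a transposase-derived gene that starts 540 bp from EIF4E2, was at 9.03% in 4EHP-knockdown and 10.3% in double-knockdown cells. SNORC (C2orf82), whose annotated start lies inside GIGYF2, was at 3.19% in GIGYF2-knockdown cells. KCNJ13, a potassium channel gene inside GIGYF2 on the opposite strand, had 16 reads in Control and 0 in GIGYF2-knockdown cells, at least 5.3-fold lower against a floor of 3 reads over the group. Of 2 genes outside the list of neighbours, AC073254.1, whose 3′ end overlaps that of EIF4E2, was at 1.24% in 4EHP-knockdown and 0.72% in double-knockdown cells, and AC064852.4, inside GIGYF2, was at 7.24% in GIGYF2-knockdown cells. EFHD1, 56005 bp from EIF4E2, fell to 74.5% in 4EHP-knockdown and 76.4% in double-knockdown cells, and to 80.9% in GIGYF2-knockdown cells. CCNO, 74042 bp from DHX29, was at 93.4% in DHX29-knockdown cells (adjusted p = 0.567). Of the 7 tested neighbours on the list, 1 was higher and 2 lower with DHX29-knockdown, 2 and 3 with GIGYF2-knockdown, 2 and 2 with 4EHP-knockdown, and 0 and 4 with both, the same counts when adjusted over the list alone. The strand setting of the counting is not given in the sources used here, so reads of genes that overlap a target may partly belong to the target. Reads of PLPP1 may likewise partly belong to MTREX.

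**Figure D1:**
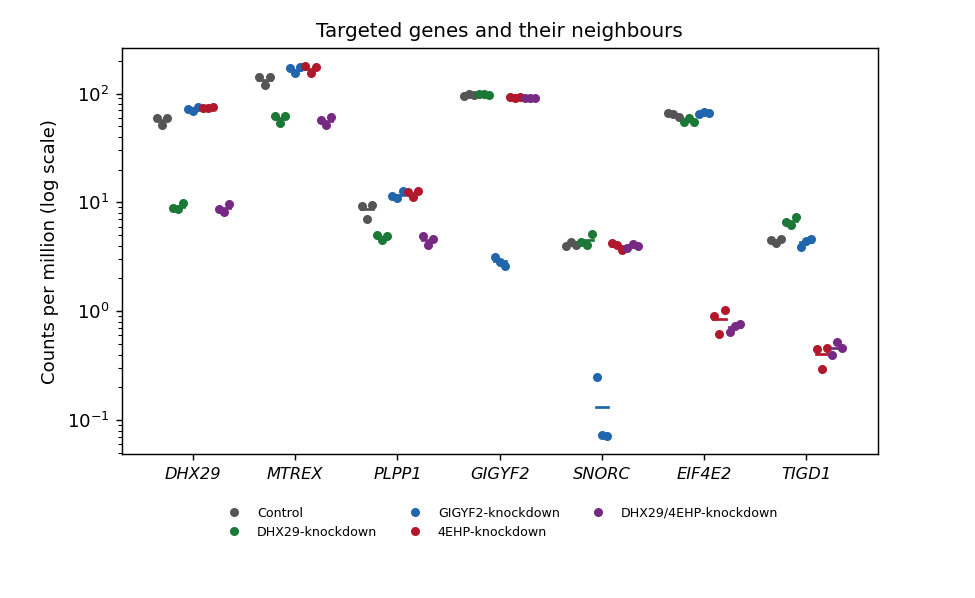
Expression in CPM on a log axis of the 3 targeted genes and of 4 neighbours in each of the 15 libraries, with 1 point per library and a line at the mean of each group of 3. DHX29, MTREX and PLPP1 are low in both groups that carry DHX29 in their name, with DHX29 at 16.1% and MTREX at 44.2% of Control in DHX29-knockdown cells, and EIF4E2 and TIGD1 are low in both groups that carry 4EHP.

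With DHX29-knockdown REL, an NF-kB subunit, rose 2.85-fold (log2 fold change 1.51 ± 0.153, 31.3 ± 1.11 against 10.9 ± 2.76 CPM, adjusted p = 1.25e-05). PGM2L1, which makes a glucose bisphosphate, rose 2.69-fold (1.43 ± 0.127), PHACTR3, a regulator of phosphatase and actin, 3.30-fold (1.72 ± 0.259), and the long non-coding RNA LINC00342 2.82-fold (1.498 ± 0.13). OSGIN1, an oxidative stress gene, fell by 1.41 ± 0.206 on the log2 scale (0.902 ± 0.376 against 2.43 ± 0.327 CPM, adjusted p = 1.78e-05). None of these changes was particular to DHX29-knockdown. With GIGYF2-, 4EHP- and double knockdown the log2 fold changes were 1.293, 1.237 and 1.205 for REL and 1.298, 1.108 and 1.121 for PGM2L1. They were 1.097, 1.08 and 1.168 for PHACTR3, 0.96, 0.837 and 0.83 for LINC00342, and -1.408, -0.801 and -1.762 for OSGIN1.

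Cholesterol and fatty acid synthesis had 12 of 31 tested genes higher and 0 lower (12 and 1 adjusted over the list alone; camera adjusted p = 0.000452, adjusted p = 0.342 with an estimated correlation). Its members STARD4, a sterol carrier, HMGCS1 and IDI1, enzymes of the mevalonate pathway, rose 2.28-, 1.38- and 1.36-fold. Among 46 genes of CCR4-NOT and mRNA decay, 11 rose and 14 fell (12 and 17 adjusted over the list alone; camera adjusted p = 0.896). XRN1, the 5′ to 3′ exonuclease, was 2.21-fold higher (log2 1.15 ± 0.080, adjusted p = 4.50e-09), and the nonsense-mediated decay factors SMG1 and UPF2 were 1.62- and 1.499-fold higher. Members of lists were named by the size of their change, so they do not show the direction of a list. XRN1 rose about as much with GIGYF2-, 4EHP- and double knockdown (log2 1.002, 1.017 and 1.007), as did SMG1 (0.679, 0.681 and 0.555) and UPF2 (0.622, 0.608 and 0.564). Ribosome collision and quality control had 9 higher and 12 lower of 30 (9 and 14 adjusted over the list alone; camera adjusted p = 0.778). LTN1, the ubiquitin ligase of stalled nascent chains, was 1.71-fold and ASCC3, a helicase that splits collided ribosomes, 1.38-fold higher. Of 42 translation initiation factors, 9 rose and 17 fell (11 and 17 adjusted over the list alone; camera adjusted p = 0.255). EIF5B was 1.43-fold and EIF3A 1.30-fold higher, and EIF3I was at 0.802 times Control. The 21 tested genes of the 4EHP-GIGYF complex and its partners held 7 higher and 4 lower ones under both adjustments (camera adjusted p = 0.635). The Argonaute gene AGO4 was 1.21-fold higher. With an offset for transcript GC and length, added after seeing the data, decay genes had 6 higher and 18 lower, collision genes 2 and 6, initiation factors 3 and 24, and the complex and its partners 3 and 7 (camera adjusted p = 0.0572, 0.241, 1.28e-06 and 0.502).

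Cytosolic ribosomal proteins fell by small steps: 0 of 79 genes were higher and 63 lower (71 adjusted over the list alone), with a median log2 fold change of -0.15 (camera adjusted p = 5.62e-16, adjusted p = 0.342 with an estimated correlation). With the offset 34 were lower. Of 36 S phase and replication genes 3 rose and 24 fell (3 and 25 adjusted over the list alone; camera adjusted p = 0.000138, adjusted p = 0.168 with an estimated correlation). The replication factors RFC2 and GINS2 fell to 0.785 and 0.818 times Control, while POLA1, the catalytic subunit of polymerase alpha, rose (log2 0.32 ± 0.048). Mitosis genes rose in 19 and fell in 8 of 38 cases (20 and 10 adjusted over the list alone; camera adjusted p = 0.00277, adjusted p = 0.513 with an estimated correlation). With the offset 13 rose and 6 fell, and the median went from 0.24 to 0.093 (camera adjusted p = 0.00373). The kinesins KIF14 and KIF11 were 2.33- and 1.74-fold and the kinetochore gene CENPF 1.64-fold higher. ATF4 targets were higher in 4 and lower in 25 of 35 cases under both adjustments (median -0.23; camera adjusted p = 1.00e-05, adjusted p = 0.342 with an estimated correlation). SLC7A11, the cystine transporter, rose 1.99-fold, whereas its partner chain SLC3A2 fell to 0.739 times Control. Numbered zinc finger genes, mostly KRAB repressors, rose in 130 and fell in 45 of 399 cases (133 and 49 adjusted over the list alone; camera adjusted p = 0.00128, adjusted p = 0.365 with an estimated correlation), and in 70 and 43 with the GC and length offset (camera adjusted p = 0.104). ZNF117, ZNF430 and ZNF91 rose 2.45-, 2.26- and 2.17-fold. The endoplasmic reticulum unfolded protein response had 5 higher and 11 lower of 23 (6 and 12 adjusted over the list alone; camera adjusted p = 0.369), with DNAJC3 1.38-fold and HSP90B1 1.28-fold higher. The heat shock response had 4 higher and 9 lower of 18 under both adjustments (camera adjusted p = 0.635), with HSPH1 1.30-fold higher and HSPA1A at 0.832 times Control. With the offset both of these lists had 2 higher and 5 lower, and S phase genes 1 and 18 (camera adjusted p = 0.211, 0.45 and 7.63e-05).

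In all, edgeR called 3471 genes higher and 4015 lower with DHX29-knockdown, of which 1081 and 56 changed at least 1.5-fold. With RLE size factors the counts were 3626 higher and 3446 lower. Without Control replicate 2, 4471 genes were called (3022 higher, 1449 lower), and 4362 of the 7486 were kept.

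With GIGYF2-knockdown a few genes were many times higher and most of the tested ATF4 targets were lower. SLC25A46 (ENSG00000164209.16, chromosome 5, 110738136 to 110765161), which encodes a mitochondrial outer membrane protein, went from 1.80 ± 0.331 to 57.1 ± 1.33 CPM, 31.5-fold higher (log2 4.98 ± 0.088, adjusted p = 6.57e-21). RCBTB1 (chromosome 13, 49531946 to 49585583) rose 8.59-fold (3.10 ± 0.078), the antisense transcript TRIM52-AS1 5.96-fold (2.58 ± 0.144), and ZWILCH, a kinetochore gene (chromosome 15, 66504959 to 66550128), 5.45-fold (2.45 ± 0.071). PHGDH, the first enzyme of serine synthesis, fell from 113 ± 5.42 to 19.8 ± 1.30 CPM (log2 -2.51 ± 0.054, adjusted p = 3.25e-19). STC2, a secreted glycoprotein, ASS1, an enzyme of arginine synthesis, and TF, transferrin, had log2 fold changes of -2.83 ± 0.097, -2.63 ± 0.105 and -2.49 ± 0.131.

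Of the 35 tested ATF4 targets 1 was higher and 30 lower under both adjustments, with a median log2 fold change of -0.59 (camera adjusted p = 1.74e-25, adjusted p = 0.0105 with an estimated correlation). STC2 and PHGDH were the members with the largest falls, followed by CHAC1, which degrades glutathione, at 0.239 times Control, and the lipoprotein receptor VLDLR at 0.251 times. ATF4 itself was at a log2 fold change of -0.31 and ASNS, asparagine synthetase, at -1.52, both read after the list was seen. The mRNA of EIF4EBP1, which binds eIF4E, fell to 0.681 times Control, and the 4EHP-GIGYF complex and partners had 6 higher and 3 lower of 21 under both adjustments, GIGYF2 itself among the lower (camera adjusted p = 0.755).

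Cytosolic ribosomal proteins had 0 higher and 61 lower genes (65 adjusted over the list alone; median -0.17; camera adjusted p = 3.18e-18, adjusted p = 0.22 with an estimated correlation), with RPL3 at 0.795 times Control. Decay genes had 13 higher and 16 lower (13 and 19 adjusted over the list alone; camera adjusted p = 0.859), and XRN1, SMG1, UPF3B and UPF2 rose 2.00-, 1.60-, 1.58- and 1.54-fold. Ribosome collision genes had 8 higher and 8 lower (9 and 9 adjusted over the list alone; camera adjusted p = 0.894), with LTN1 1.62- and ASCC3 1.504-fold higher. Initiation factors had 13 higher and 17 lower (14 and 17 adjusted over the list alone; camera adjusted p = 0.799), with DENR, a reinitiation factor, 1.32-fold higher. S phase genes had 5 higher and 17 lower (5 and 20 adjusted over the list alone; camera adjusted p = 0.00565, adjusted p = 0.22 with an estimated correlation). Mitosis genes had 15 and 9 (16 and 9 adjusted over the list alone; camera adjusted p = 0.0556), with KIF14 2.26-fold and MKI67 1.57-fold higher. Cholesterol genes had 12 higher and 6 lower under both adjustments (camera adjusted p = 0.433), with STARD4 2.15-fold higher. With the offset decay genes had 8 higher and 21 lower, collision genes 3 and 6, initiation factors 6 and 18, mitosis genes 11 and 9, S phase genes 2 and 13 and the complex and its partners 1 and 6 (camera adjusted p = 0.068, 0.901, 0.0347, 0.207, 0.0442 and 0.25). In all, 3993 genes were called higher and 4063 lower, 1139 and 287 of them by at least 1.5-fold. With RLE size factors the counts were 4180 and 3694.

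With 4EHP-knockdown SLC25A46 rose 29.95-fold (log2 4.91 ± 0.088, adjusted p = 8.60e-21), RCBTB1 8.59-fold (3.10 ± 0.078), TRIM52-AS1 5.59-fold (2.48 ± 0.142) and ZWILCH 5.56-fold (2.47 ± 0.071). LCTL, a lactase-like gene that overlaps ZWILCH on the opposite strand and whose reads may partly be those of ZWILCH, rose 5.18-fold, and SGK223 (PRAG1), a pseudokinase gene, 4.70-fold (2.23 ± 0.162). ASS1, STC2, TF, PHGDH and CHAC1 had log2 fold changes of -2.51 ± 0.1, -2.46 ± 0.09, -2.42 ± 0.126, -2.25 ± 0.052 and -2.24 ± 0.154.

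**Figure D2:**
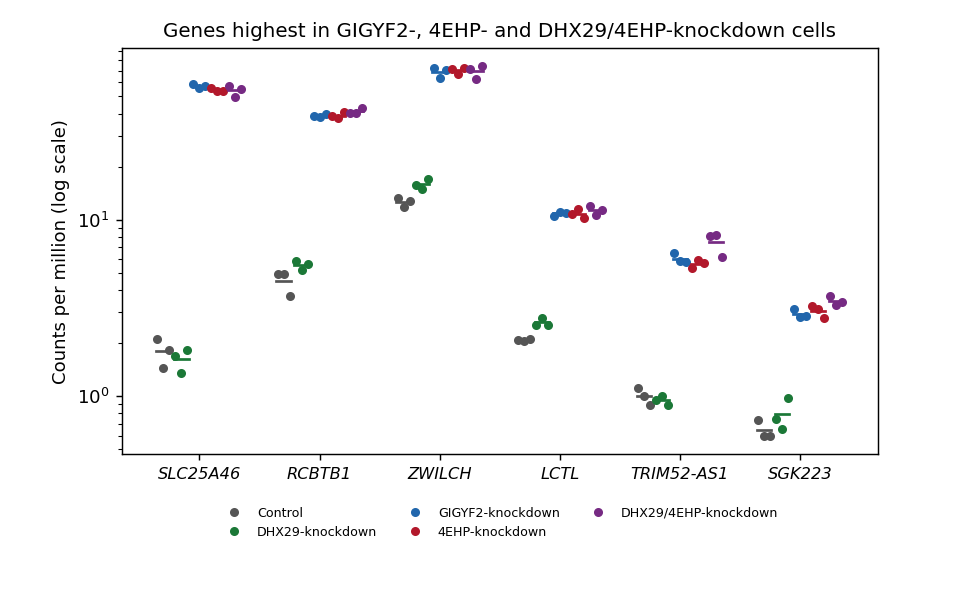
Expression in CPM on a log axis of 6 genes in each of the 15 libraries, with 1 point per library and a line at the mean of each group of 3. SLC25A46 is at 1.80 CPM in Control and 1.62 CPM in DHX29-knockdown cells, and at 57.1, 54.3 and 54.1 CPM in GIGYF2-, 4EHP- and DHX29/4EHP-knockdown cells.

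ATF4 targets were again 1 higher and 30 lower of 35 under both adjustments (median -0.59; camera adjusted p = 1.13e-26, adjusted p = 0.00842 with an estimated correlation), and VLDLR was at 0.282 times Control. Cytosolic ribosomal proteins had 0 higher and 59 lower (64 adjusted over the list alone; median -0.15; camera adjusted p = 2.05e-17, adjusted p = 0.262 with an estimated correlation). Mitosis genes had 16 higher and 8 lower (17 and 8 adjusted over the list alone; camera adjusted p = 0.0056, adjusted p = 0.478 with an estimated correlation), with KIF14 2.34-fold and ECT2, a cytokinesis factor, 1.65-fold higher. Decay genes had 12 higher and 14 lower (13 and 15 adjusted over the list alone; camera adjusted p = 0.962), with XRN1 2.02-fold higher. Ribosome collision genes had 9 higher and 9 lower (9 and 10 adjusted over the list alone; camera adjusted p = 0.763), with ASCC3 and LTN1 1.62- and 1.65-fold higher. The heat shock response had 8 higher and 3 lower of 18 (8 and 4 adjusted over the list alone; camera adjusted p = 0.105), with HSPA4L 1.46-fold and HSPH1 1.44-fold higher. With the offset decay genes had 7 higher and 20 lower, collision genes 6 and 6, heat shock genes 8 and 1 and mitosis genes 13 and 6 (camera adjusted p = 0.113, 0.822, 0.00306 and 0.0191). In all, 3748 genes were called higher and 3601 lower, 954 and 228 of them by at least 1.5-fold.

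In the double knockdown against Control SLC25A46 rose 29.8-fold (log2 4.90 ± 0.088, adjusted p = 8.90e-21), RCBTB1 9.08-fold (3.18 ± 0.077), TRIM52-AS1 7.43-fold (2.89 ± 0.138), ZWILCH 5.48-fold (2.46 ± 0.071) and SGK223 5.33-fold (2.42 ± 0.159). TF, ASS1, STC2 and PHGDH had log2 fold changes of -2.43 ± 0.126, -2.37 ± 0.099, -2.13 ± 0.087 and -2.09 ± 0.052. CXCL8, the neutrophil-attracting cytokine, rose 2.24-fold (1.16 ± 0.215).

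Cholesterol and fatty acid synthesis had 19 of 31 genes higher and 3 lower (21 and 3 adjusted over the list alone; median 0.14; camera adjusted p = 4.35e-06, adjusted p = 0.122 with an estimated correlation). STARD4 was 2.47-fold and MSMO1, a sterol oxidase, 1.43-fold higher. ATF4 targets had 1 higher and 29 lower under both adjustments (median -0.51; camera adjusted p = 2.68e-23, adjusted p = 0.0146 with an estimated correlation). Cytosolic ribosomal proteins had 0 higher and 60 lower (63 adjusted over the list alone; camera adjusted p = 3.90e-17, adjusted p = 0.238 with an estimated correlation). S phase genes had 3 higher and 16 lower (3 and 17 adjusted over the list alone; camera adjusted p = 0.00325, adjusted p = 0.149 with an estimated correlation), and mitosis genes 15 and 6 under both adjustments (camera adjusted p = 0.0111, adjusted p = 0.456 with an estimated correlation). With the offset mitosis genes had 13 higher and 10 lower, and their median went from 0.18 to 0.035. Target neighbours as a list were lower (camera adjusted p = 0.00396, adjusted p = 0.122 with an estimated correlation). In all, 4224 genes were called higher and 3908 lower, 1118 and 262 of them by at least 1.5-fold.

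The double against the DHX29-knockdown compares cells with and without lowered 4EHP where DHX29 was already low, with no Control library. Here SLC25A46 was 33.3-fold higher (log2 5.06 ± 0.091, adjusted p = 9.50e-21), TRIM52-AS1 7.86-fold, RCBTB1 7.38-fold and SGK223 4.399-fold. ASS1 and TF were lower (log2 -2.203 ± 0.1 and -1.96 ± 0.13). ASNSP1, a pseudogene of ASNS whose reads may come from ASNS, fell by 2.04 ± 0.24. ATF4 targets had 1 higher and 28 lower genes (1 and 29 adjusted over the list alone; median -0.37; camera adjusted p = 5.07e-36, adjusted p = 0.0026 with an estimated correlation). Of the 35 members, 26 were lower both here and in 4EHP-knockdown against Control. The 4EHP-GIGYF complex and partners, which include EIF4E2 itself, had 0 higher and 9 lower (11 adjusted over the list alone; camera adjusted p = 2.97e-06, adjusted p = 0.00984 with an estimated correlation). Replication-dependent histones had 24 of 58 genes higher and 0 lower (28 and 1 adjusted over the list alone; median 0.26; camera adjusted p = 2.70e-13, adjusted p = 0.0264 with an estimated correlation). These mRNAs mostly lack poly(A), and replicate 2 of the double knockdown stood apart from its group (chi-square per degree of freedom 7.66 and 6.87). Here 1472 genes were called higher and 1161 lower, 156 and 149 by at least 1.5-fold. Without DHX29-knockdown replicate 1 or 3, 1606 or 1654 genes were called. The GC and length offset gave 3194 and replicates 1 and 3 of each group 3403, both alternatives added after seeing the data. A larger count, from a replicate block, is given below beside the check of pairing.

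**Figure D3:**
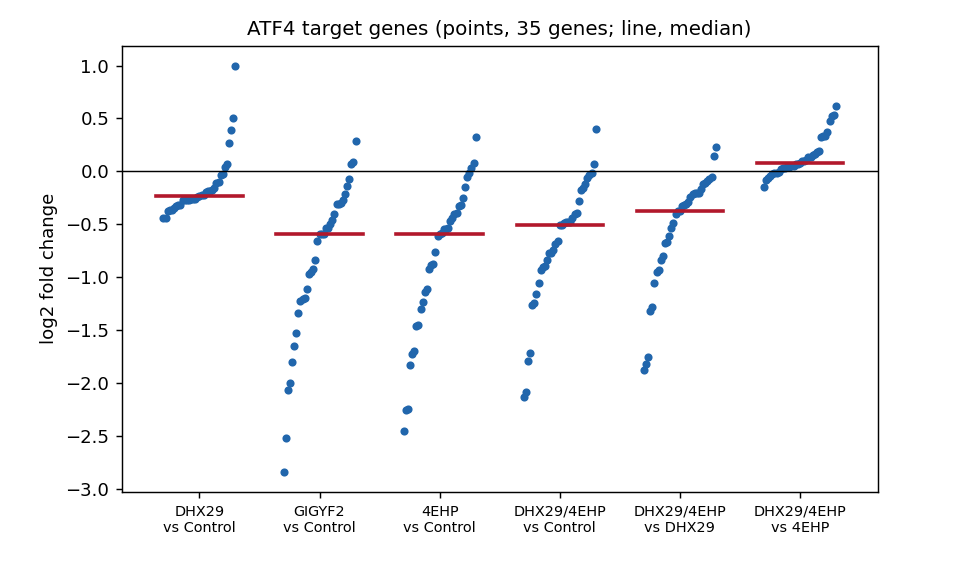
Log2 fold changes of 35 ATF4 target genes (points, sorted within each comparison; line, median) in 6 comparisons. The medians are -0.23 for DHX29, -0.59 for GIGYF2, -0.59 for 4EHP and -0.51 for DHX29/4EHP against Control, -0.37 for the double against the DHX29-knockdown and 0.08 for the double against the 4EHP-knockdown.

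Where DHX29 was lowered with 4EHP already low (double against 4EHP-knockdown), fewer genes differed: 280 were called higher and 87 lower, 37 and 9 by at least 1.5-fold. MTREX, beside DHX29, and PLPP1, whose 3′ end overlaps that of MTREX, fell by 1.59 ± 0.091 and 1.42 ± 0.102 on the log2 scale, DHX29 itself by 3.06 ± 0.064. AIF1, a calcium-binding myeloid protein gene, rose 1.95-fold (log2 0.96 ± 0.134, adjusted p = 0.000266). Cholesterol and fatty acid synthesis had 7 higher and 0 lower genes (14 and 0 adjusted over the list alone; median 0.11; camera adjusted p = 1.07e-14, adjusted p = 0.00936 with an estimated correlation). Granulocyte and monocyte genes had 3 of 14 higher and 0 lower (8 and 0 adjusted over the list alone; median 0.36; camera adjusted p = 2.38e-08, adjusted p = 0.00218 with an estimated correlation). Erythroid genes had 0 of 42 higher and 7 lower (0 and 9 adjusted over the list alone; camera adjusted p = 0.000278, adjusted p = 0.0527 with an estimated correlation), and megakaryocytic genes 1 of 15 higher and 0 lower under both adjustments (camera adjusted p = 0.0336, adjusted p = 0.0996 with an estimated correlation). ATF4 targets had 8 higher and 0 lower (13 and 1 adjusted over the list alone; camera adjusted p = 2.38e-08, adjusted p = 0.0458 with an estimated correlation). Cytokines had 3 of 10 higher and 0 lower (5 and 0 adjusted over the list alone; camera adjusted p = 0.00016, adjusted p = 0.0103 with an estimated correlation). Interferon-stimulated genes had 4 higher and 1 lower of 25 (5 and 1 adjusted over the list alone; camera adjusted p = 0.0114, adjusted p = 0.0375 with an estimated correlation). Lists below the other genes were initiation factors with 0 higher and 2 lower (0 and 4 adjusted over the list alone; camera adjusted p = 0.000235, adjusted p = 0.0101 with an estimated correlation). So were decay genes with 1 and 1 (2 and 5 adjusted over the list alone; camera adjusted p = 0.0089, adjusted p = 0.0264 with an estimated correlation) and heat shock genes with 0 and 1 under both adjustments (camera adjusted p = 0.000271, adjusted p = 0.0101 with an estimated correlation), and the target neighbours, MTREX and PLPP1 among them, with 0 and 2 under both (camera adjusted p = 0.00228, adjusted p = 0.0352 with an estimated correlation). S phase genes had 1 and 2 under both (camera adjusted p = 0.00201, adjusted p = 0.0527 with an estimated correlation) and snoRNA hosts 0 and 0 (0 and 1 adjusted over the list alone; camera adjusted p = 0.00718, adjusted p = 0.197 with an estimated correlation). With the offset decay genes had 1 higher and 5 lower. Without 4EHP-knockdown replicate 1 or 3, 154 or 140 genes were called, without double-knockdown replicate 1 or 3, 233 or 243, and with the libraries of these 2 groups alone, 153. With the GC and length offset 781 genes were called, and with replicates 1 and 3 of each group 865, both alternatives added after seeing the data. More were called with a replicate block, whose count is given below beside the check of pairing.

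Knockdown of the 2 partners of the repressor complex differed in 40 genes: 27 were higher and 13 lower in GIGYF2- than in 4EHP-knockdown cells, 8 and 5 by at least 1.5-fold. EIF4E2 and TIGD1 were 77.0- and 10.6-fold higher, and GIGYF2 and SNORC were lower by log2 values of -5.01 ± 0.055 and -4.86 ± 0.238. FAM13B was at 36.6 ± 1.18 against 20.1 ± 0.539 CPM (1.82-fold, log2 0.87 ± 0.065, adjusted p = 2.42e-08). The median log2 difference between these groups was -0.03 over the 35 ATF4 targets and -0.01 over the 79 ribosomal protein genes. Megakaryocytic genes had 0 higher and 1 lower of 15 (0 and 3 adjusted over the list alone; median -0.17; camera adjusted p = 0.00014, adjusted p = 0.0405 with an estimated correlation). Without replicates 1, 2 or 3 of GIGYF2-knockdown 23, 24 or 22 genes were called, and without replicate 1 or 3 of 4EHP-knockdown 24 or 22. The count was 98 with no filter on low counts, 99 with the GC and length offset and 181 with replicates 1 and 3, the last 2 alternatives added after seeing the data. A replicate block called more genes than any of these, and its count is given below beside the check of pairing.

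DHX29- and 4EHP-knockdown cells differed in 2751 genes, 1307 higher and 1444 lower with DHX29-knockdown, 237 and 113 by at least 1.5-fold. ASS1 and STC2 were 5.07- and 4.59-fold higher with DHX29- than with 4EHP-knockdown (log2 2.34 ± 0.101 and 2.199 ± 0.092), and SLC25A46, RCBTB1, TRIM52-AS1 and ZWILCH were lower by log2 values of -5.06 ± 0.091, -2.80 ± 0.076, -2.56 ± 0.146 and -2.15 ± 0.069. ATF4 targets were higher in 31 and lower in 1 of 35 cases (33 and 1 adjusted over the list alone; median 0.42; camera adjusted p = 3.10e-42, adjusted p = 0.00142 with an estimated correlation). Histones were higher in 2 and lower in 25 of 58 (2 and 26 adjusted over the list alone; camera adjusted p = 2.19e-12, adjusted p = 0.0214 with an estimated correlation). Erythroid genes were so in 1 and 15 of 42 (2 and 16 adjusted over the list alone; camera adjusted p = 2.76e-07, adjusted p = 0.0214 with an estimated correlation). Granulocyte and monocyte genes were higher in 4 and lower in 0 of 14 under both adjustments (camera adjusted p = 0.0087, adjusted p = 0.0384 with an estimated correlation). Heat shock genes were higher in 0 and lower in 4 of 18 (0 and 7 adjusted over the list alone; camera adjusted p = 6.85e-06, adjusted p = 0.00484 with an estimated correlation). Mitochondrially encoded mRNAs were so in 9 and 1 of 13 (10 and 1 adjusted over the list alone; camera adjusted p = 2.13e-10, adjusted p = 0.0384 with an estimated correlation). Initiation factors were so in 3 and 11 of 42 (3 and 12 adjusted over the list alone; camera adjusted p = 0.00431, adjusted p = 0.0248 with an estimated correlation). S phase genes were so in 2 and 9 of 36 (2 and 10 adjusted over the list alone; camera adjusted p = 0.00111, adjusted p = 0.0478 with an estimated correlation). The complex and its partners, EIF4E2 included, were so in 4 and 0 of 21 (6 and 0 adjusted over the list alone; camera adjusted p = 0.000391, adjusted p = 0.0214 with an estimated correlation). With the offset heat shock genes had 0 higher and 7 lower and S phase genes 3 and 15. Without DHX29-knockdown replicate 1 or 3, 1760 or 1768 genes were called. The GC and length offset gave 3611 and replicates 1 and 3 of each group 3664, both alternatives added after seeing the data. The count with a replicate block was larger still and is given below beside the check of pairing.

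The interaction asks whether the double knockdown departs from the sum of the single ones. The double knockdown was lower than the sum for 2469 genes and higher for 1564, 960 and 59 by at least 1.5-fold. PHACTR3 and REL lay below the sum by log2 values of -1.64 ± 0.344 and -1.54 ± 0.207. So did KCNIP4, a potassium channel regulator, and MCTP1, a calcium-binding membrane protein gene, by -1.69 ± 0.377 and -1.56 ± 0.321. In the order PHACTR3, REL, KCNIP4 and MCTP1, the log2 fold changes against Control were 1.724, 1.511, 1.354 and 1.261 with DHX29-knockdown. They were 1.08, 1.237, 1.059 and 1.133 with 4EHP-knockdown and 1.168, 1.205, 0.729 and 0.832 with both. The double knockdown thus lay near or below the single rises for these genes, and not below Control. STK19B, a pseudogene of STK19 whose reads may be shared with it, and ICOSLG, a T cell costimulator, lay above it by 2.69 ± 0.498 and 1.21 ± 0.313. The value of ICOSLG is that of the identifier ENSG00000277117.4 alone. Ribosomal protein genes were higher than the sum in 38 and lower in 0 of 79 cases (50 and 0 adjusted over the list alone; camera adjusted p = 2.01e-13, adjusted p = 0.32 with an estimated correlation). ATF4 targets were so in 26 and 3 of 35 (27 and 3 adjusted over the list alone; camera adjusted p = 6.35e-10, adjusted p = 0.25 with an estimated correlation). Mitosis genes were so in 2 and 16 of 38 (3 and 17 adjusted over the list alone; camera adjusted p = 0.00107, adjusted p = 0.335 with an estimated correlation). With the offset ribosomal protein genes were higher than the sum in 22 and lower in 0 cases and mitosis genes in 2 and 8, and the medians went from 0.154 to 0.065 and from -0.247 to -0.081. With RLE size factors 975 genes were higher and 2577 lower, and without Control replicate 2 or double-knockdown replicate 2, 2531 (331 and 2200) or 2675 (421 and 2254) were called. With the GC and length offset 2458 were called, of which 1520 were among the 4033 in the same direction.

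The GC3 index sets genes with A or U at the third codon position, a composition linked to lower mRNA stability in human cells, against those with G or C. Its mean was 0.751 ± 0.108 (SD, n = 3) in Control, 1.17 ± 0.065 in DHX29-, 1.15 ± 0.070 in GIGYF2-, 1.16 ± 0.061 in 4EHP- and 1.08 ± 0.136 in DHX29/4EHP-knockdown cells. Each of the 4 differences from Control, 0.42, 0.40, 0.41 and 0.33, had no overlap between the groups and an exact two-sided permutation p = 0.1, the smallest that 3 against 3 allow (0.2 adjusted over the 8 pairs). Of the 2508 genes with the lowest GC3, 64.2% were higher and 3.2% lower with DHX29-knockdown, and of the 2508 with the highest, 2.0% were higher and 31.5% lower. Camera with an estimated correlation gave p = 0.0269, 0.0423, 0.0316 and 0.0594 for the low-GC3 genes in the 4 comparisons with Control, and p = 0.145, 0.227, 0.192 and 0.372 for the high-GC3 genes. Replicate 2 had the lowest index of its group in all 5 groups (0.633, 1.10, 1.07, 1.09 and 0.921). The trend was not limited to codons. Across 1851 long non-coding RNA genes Spearman's rho between transcript GC and the log2 fold change was -0.40, -0.32, -0.32 and -0.30, beside -0.51, -0.46, -0.49 and -0.40 for GC3 across coding genes, though genes are not independent replicates. The index from GC3 beyond what 3′ UTR GC and transcript length predict differed from Control by 0.19, 0.20, 0.21 and 0.16. That prediction leaves out the GC of the rest of the transcript, so these values do not single out codons. An index built on the GC of the whole transcript differed by 0.448, 0.407, 0.417 and 0.341. With the GC and length offset, 3935 of the 7486 calls of DHX29-knockdown were kept in the same direction, 5190 of 8056 for GIGYF2, 4397 of 7349 for 4EHP and 5752 of 8132 for the double knockdown.

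**Figure D4:**
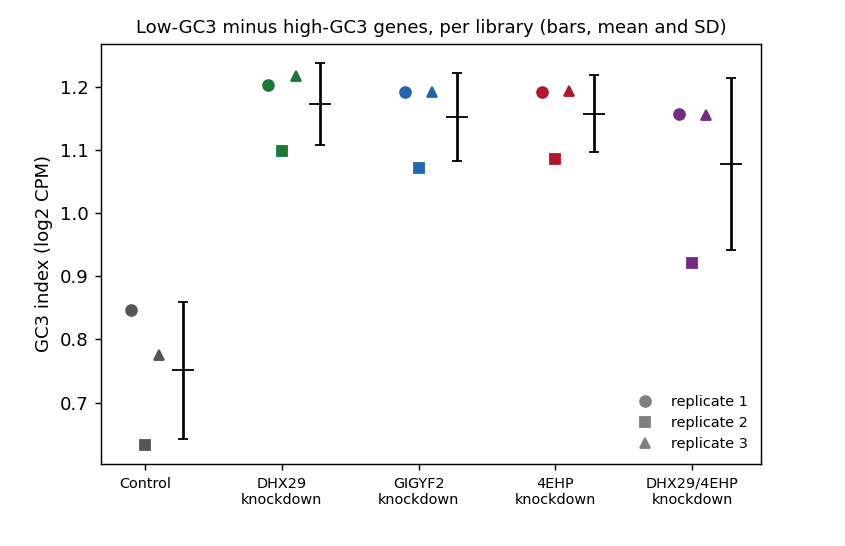
GC3 index (mean log2 CPM of low-GC3 genes minus that of high-GC3 genes) of each of the 15 libraries by group, with a marker for each replicate number and the mean and SD of each group beside. Control lies at 0.751, the knockdown groups lie between 1.08 and 1.17, and replicate 2 is the lowest of its group in all 5 groups.

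Log2 fold changes against Control were alike between knockdowns. Across genes, Pearson's r was 0.78 between GIGYF2 and 4EHP, 0.83 between 4EHP and the double, 0.72 between GIGYF2 and the double, 0.67 between DHX29 and the double, 0.65 between DHX29 and 4EHP and 0.63 between DHX29 and GIGYF2. Simulated experiments with no change against 3 shared controls gave r = 0.51 ± 0.013 (SD, 20 simulations) and a covariance of 0.0246, so part of these correlations may come from the shared Control libraries, which are too few to give each comparison at least 2 of its own. Beyond the simulated covariance, 0.0851 remained for GIGYF2 with 4EHP, 0.0847 for 4EHP with the double, 0.0801 for GIGYF2 with the double, 0.0588 for DHX29 with GIGYF2, 0.0578 for DHX29 with the double and 0.0526 for DHX29 with 4EHP. The simulation held only noise around the Control means. A displaced Control group or a GC bias of the libraries therefore stays in these values, which do not estimate a common effect alone. GIGYF2 and 4EHP shared 3272 higher genes (690.9 if independent), 2955 lower ones (675.4) and 1 gene called in opposite directions. Both comparisons use the same Control libraries, so they are not independent. A displaced Control or a GC bias enters these overlaps too, and their excess does not measure a common effect alone. Comparisons that share no library gave r = 0.32 (covariance 0.0322) for 4EHP against Control with the double against DHX29, 0.19 (covariance 0.0214) for GIGYF2 against Control with the same, and 0.074 (covariance 0.00524) for DHX29 against Control with the double against 4EHP.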

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

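The tests that set Control apart, those on MTREX and all on guides acting off target were chosen only after the result was seen, as were the GC and length offset itself, the count of kept interaction calls and the limit of the copy number test, first set beforehand for 17 genes, to 10 of them, while the tests on non-coding genes, on ATF4 targets with the offset and on other splits were set before their results. The interaction stands out because the test of the difference itself, between the effect of 4EHP-knockdown with and without DHX29, called 4033 genes. The named ones were STK19B (2.69), LINC00634 (1.30), ICOSLG (1.21), LMF1 (1.08), KCNIP4 (-1.69), PHACTR3 (-1.64), MCTP1 (-1.56) and REL (-1.54), as log2 differences. The call of LINC00634 was lost with RLE size factors (adjusted p = 0.0562), with the offset (adjusted p = 0.102) and on leaving out any 1 of 11 libraries (adjusted p = 0.055 to 0.144). The call of LMF1 was lost with the offset (adjusted p = 0.0755), with no low-count filter (adjusted p = 0.0652), with replicates 1 and 3 (adjusted p = 0.0691) and on leaving out any 1 of 5 libraries.

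The interaction and the changes common to all 4 knockdowns run with GC content, and a GC bias of the libraries predicts the trend in genes with no codons, where rho with transcript GC over the mean of the 4 knockdowns was -0.358 (1851 genes, bootstrap SD 0.021). It does not account for the lower ATF4 targets, whose median in 4EHP-knockdown against Control was -0.527 with the offset (SD of members 0.685). A displaced Control group does not account for all of their fall. Their median was -0.373 in the double against the DHX29-knockdown, with no Control library. A displaced Control may still add to the fall against Control. A feature common to the Control and DHX29-knockdown libraries would lower them in both comparisons and was not tested. For the interaction the bound set beforehand asked whether over 50% of the count was left with the offset, and 60.9% was. That bound used the wrong measure, because only 37.7% of the 4033 calls were kept in the same direction and the rest of the 2458 were other genes, so the kept share, chosen after the result was seen, leaves GC bias and a joint effect of both depletions open. A displaced Control group, which also enters the interaction, stays open there as well. Control libraries standing apart also cannot be told apart from 4 knockdowns acting alike, since the knockdown groups differ by at most 0.096 in the GC3 index, less than 1 SD of Control, and both readings need that.

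MTREX fell wherever DHX29 was targeted. MTREX fell by log2 values of -1.18 against Control and -1.587 in the double against the 4EHP-knockdown, and did not fall in GIGYF2- and 4EHP-knockdown cells (0.31 and 0.33). Guides acting on the promoter region that both genes share would give these values. A fall of MTREX that follows the loss of DHX29 would give them too, so they do not decide between these readings. Under either reading, part of the DHX29 profile may be a loss of MTREX. If it were, non-coding RNAs that the nuclear exosome degrades would rise against coding genes, and the median of 1851 non-coding genes minus that of coding genes was 0.02 in the double against the 4EHP-knockdown, which lies between the bounds set for a loss and for none. Effects of DHX29 and of MTREX therefore cannot be told apart in these libraries.

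In all, 17 genes were at least 4-fold higher in 4EHP-knockdown than in Control cells, and 10 of them, among them SLC25A46, RCBTB1 and ZWILCH, were called higher in the double against the DHX29-knockdown. A difference in copy number of a whole region between clones would raise the neighbours of the 10 about as much as the 10 themselves. The 10 had a median log2 fold change of 2.472 in that comparison. Yet 133 other tested genes within 500 kb, with all 17 left out, had a median of 0.097 (SD 0.379), at most 0.148 around any member. Of these, 17.3% were called higher against 6.8% of all tested genes. Among the 10, LCTL overlaps ZWILCH and RP11-337N6.3 lies inside AC074286.1, and these overlapping genes rose together. A median over 500 kb cannot speak of a copy number change confined to 1 or a few genes. Off-target action of the 4EHP guides would leave the 10 lower with the GIGYF2 guides than with the 4EHP guides, but their median log2 difference between these groups was 0.014 (SD 0.222). A guide in the Control and DHX29-knockdown cells that silences these promoters off target stays open for the 10, of which 2 were called higher with DHX29-knockdown, because only 4 other tested genes start within 1 kb of them, with a median of 0.47, of which AGPS (0.85) and HIST1H2BN (1.10) were called higher and NFE2L2 (-0.08) and TRIM52 (0.09) were not. The other 7, at 0.024 to 0.194 CPM in Control, were all called higher with DHX29-knockdown and were left untested, and whether 4EHP and GIGYF2 repress the 10 was not tested either.

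Other splits of the libraries gave these counts. Each pairwise comparison has 10 splits of its 6 libraries, too few for a share under 0.05, and 1 split, the real one, gave as many genes in each. The real and the highest other counts were 7486 and 1 for DHX29, 8056 and 0 for GIGYF2, 7349 and 1 for 4EHP, 8132 and 0 for the double, 2633 and 2 for the double against DHX29, 367 and 2 for the double against 4EHP, 40 and 1 for GIGYF2 against 4EHP, and 2751 and 0 for DHX29 against 4EHP. For the interaction, 3 of 100 splits drawn, the real one included, gave as many as 4033 genes, a share under 0.05, with 6850 and 5600 in the other 2. Such counts point to a structure of the samples: the 5 other splits with more than 13 calls all placed the 3 Control libraries on the same side of the contrast, as the real one does, and the 76 splits that parted them called at most 1 gene. The counts of 6850 and 5600 came from the 23 other splits that kept the Control libraries together. Labels were shuffled over all Control, DHX29-, 4EHP- and double-knockdown libraries. The share therefore asks whether these groups differ in any way and does not test the interaction itself.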

How the results depend on the processing

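The GC and length offset and the fits on replicates 1 and 3 were chosen after seeing the data, and all other alternatives before. With 3 libraries per group, the smallest of the simulated changes were called in 54% of cases, so small effects are the limit. The 3 targets kept direction and call in every alternative read for single genes, which left out limma-voom and the fold threshold. The count of called genes stayed within 1.5 times under RLE size factors, DESeq2 and limma-voom in all 9 comparisons. Of 446 pairs of a named gene and a comparison, 445 were called. Of these, 398 stayed called in each alternative read for single genes and set beforehand, other than leaving out libraries, and 339 in every one read. A pair with no value counted as kept. Of the 446, 435 had a value with DESeq2 and 443 with the libraries of the comparison alone. Except where the construction shows it (fewer libraries, a fold threshold, fewer genes), the cause of a change was not tested.

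With a fold of at least 1.5 the counts were 1137 (DHX29), 1426 (GIGYF2), 1182 (4EHP), 1380 (double), 305 (double against DHX29), 46 (double against 4EHP), 13 (GIGYF2 against 4EHP), 350 (DHX29 against 4EHP) and 1019 (interaction). The libraries of the comparison alone gave 153 for the double against 4EHP, and no low-count filter gave 98 for GIGYF2 against 4EHP. The offset gave 781, 99 and 2458 for the double against 4EHP, GIGYF2 against 4EHP and the interaction, and replicates 1 and 3 gave 865 and 181 for the first 2 of these. Leaving out 1 library gave 4471 to 7293 for DHX29, 1606 to 2327 for the double against DHX29, 140 to 294 for the double against 4EHP, 22 to 27 for GIGYF2 against 4EHP, 1760 to 2295 for DHX29 against 4EHP and 2531 to 4540 for the interaction. The offset turned the sign of SEL1L (-0.011), SPRED1 (-0.106) and PDK1 (-0.189) with DHX29-knockdown, EIF4E (-0.048), AGO3 (-0.102) and CHORDC1 (-0.02) with GIGYF2-knockdown, and EIF4E (-0.02) and AGO3 (-0.083) with 4EHP-knockdown.

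The labels do not pair replicates by number. Residuals of libraries with the same number correlated at -0.034 to 0.212 between groups, over 0.1 in 10 of 30 pairs, 9 of them among the 10 pairs of replicate 2, and 12 of 15 libraries correlated best with their own number. With a replicate block 4949 genes were called for the double against DHX29, 1585 for the double against 4EHP, 397 for GIGYF2 against 4EHP, 5084 for DHX29 against 4EHP and 6809 for the interaction.

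The number of lists with a camera call fell with an estimated correlation from 8 to 0 (DHX29), 7 to 1 (GIGYF2), 6 to 1 (4EHP), 8 to 1 (double), 9 to 3 (double against DHX29), 15 to 9 (double against 4EHP) and 7 to 0 (interaction), and with fry it was 16, 20, 21, 20, 14 and 14 (without the double against 4EHP). The GC3 index difference from Control was 0.246, 0.24, 0.238 and 0.187 when genes were parted at the median, and 0.191, 0.198, 0.213 and 0.16 for residual GC3, for DHX29, GIGYF2, 4EHP and the double.

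For DHX29 with GIGYF2, DHX29 with 4EHP, GIGYF2 with 4EHP, DHX29 with the double, GIGYF2 with the double and 4EHP with the double, r was 0.781, 0.78, 0.879, 0.791, 0.845 and 0.936 in genes of at least 10 CPM, and 0.565, 0.562, 0.739, 0.615, 0.682 and 0.804 with the offset. For pairs that share no library, 4EHP and the double against DHX29, DHX29 and the double against 4EHP, and GIGYF2 and the double against DHX29, the offset gave 0.394, 0.138 and 0.244, and genes of at least 10 CPM gave 0.038 for the middle and 0.159 for the last. Spearman's rho was 0.659 for DHX29 with GIGYF2, 0.833 for GIGYF2 with 4EHP, 0.686, 0.776 and 0.81 for DHX29, GIGYF2 and 4EHP with the double, and 0.205 and 0.143 for 4EHP and GIGYF2 with the double against DHX29. Replicates 1 and 3 gave 0.603 for DHX29 with GIGYF2, 0.609 for DHX29 with 4EHP, 0.634 and 0.789 for DHX29 and 4EHP with the double, and 0.297 and 0.22 for 4EHP and GIGYF2 with the double against DHX29. Leaving out 1 library gave 0.62 to 0.688, 0.643 to 0.706, 0.77 to 0.807, 0.672 to 0.725, 0.709 to 0.752 and 0.823 to 0.849 for the 6 pairs in the first order, and 0.28 to 0.343 and 0.167 to 0.218 for 4EHP and GIGYF2 with the double against DHX29.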

Other observations

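None of the values in this part comes from a test of an explanation, and all lists in it were fixed before the data were examined. Mitochondrially encoded mRNAs were lower with GIGYF2- and 4EHP-knockdown: 10 of 13 in each (10, and 11 with 1 higher, adjusted over the list alone; camera adjusted p = 2.60e-06 and 1.56e-07, adjusted p = 0.22 and 0.262 with an estimated correlation). MT-ND6 fell by 0.67 ± 0.034 and 0.66 ± 0.034, MT-ND5 by 0.49 ± 0.026 and 0.50 ± 0.026, and MT-CYB by 0.41 ± 0.034 and 0.42 ± 0.034 on the log2 scale. With the double knockdown 7 were lower under both adjustments (camera adjusted p = 0.000191, adjusted p = 0.238 with an estimated correlation), and with DHX29-knockdown 1 was higher and 4 lower under both (camera adjusted p = 0.475). Replication-dependent histones went the other way, with 27 higher and 1 lower of 58 with GIGYF2-knockdown (28 and 1 adjusted over the list alone; camera adjusted p = 1.84e-07, adjusted p = 0.22 with an estimated correlation), 18 and 0 with 4EHP-knockdown (camera adjusted p = 7.94e-05, adjusted p = 0.262 with an estimated correlation), and 22 and 0 with both (camera adjusted p = 0.00058, adjusted p = 0.238 with an estimated correlation), the last 2 pairs under both adjustments. DHX29-knockdown had 0 higher and 10 lower (9 adjusted over the list alone; camera adjusted p = 0.164), and 1 and 6 with the GC and length offset. HIST1H2BN, a histone H2B gene, was 2.07-, 1.94- and 2.09-fold higher in the first 3 of these groups.

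Markers of the erythroid lineage of K562 cells changed in both directions. Of 42 erythroid genes, 4 were higher and 15 lower with DHX29-knockdown under both adjustments (camera adjusted p = 0.0378, adjusted p = 0.404 with an estimated correlation), 17 and 8 with GIGYF2-knockdown (23 and 9 adjusted over the list alone; camera adjusted p = 0.0468, adjusted p = 0.475 with an estimated correlation), 15 and 7 with 4EHP-knockdown (16 and 7 adjusted over the list alone; camera adjusted p = 0.0277, adjusted p = 0.364 with an estimated correlation), and 11 and 9 with both (13 and 9 adjusted over the list alone; camera adjusted p = 0.668). HBZ, embryonic zeta-globin, was at 0.825, 1.36 and 1.33 times Control with DHX29-, GIGYF2- and 4EHP-knockdown, and ALAS2, the erythroid enzyme of haem synthesis, at 1.53 times with GIGYF2-knockdown. Megakaryocytic genes had 2 higher and 6 lower of 15 with GIGYF2-knockdown and 4 and 1 with the double, in which ITGA2B, the platelet integrin, rose 1.72-fold (both counts the same adjusted over the list alone; camera adjusted p = 0.348 and 0.262). Granulocyte and monocyte genes had 7 higher and 1 lower of 14 in the double knockdown under both adjustments (camera adjusted p = 0.116), with CEBPE, LYZ and FCER1G 2.92-, 1.61- and 1.56-fold higher. Of the markers of cells other than K562, 1 of 6 tested lymphoid genes, CD7, was higher with GIGYF2-knockdown under both adjustments (camera adjusted p = 0.755), a call lost with replicates 1 and 3 (adjusted p = 0.0531), and 2 of 9 fibroblast and epithelial genes were higher and 1 lower, as many as adjusted over the list alone (camera adjusted p = 0.799). In 4EHP- and double-knockdown cells 1 lymphoid gene was higher and 1 lower under both adjustments (camera adjusted p = 0.805 and 0.404). Fibroblast and epithelial genes had 2 higher and 1 lower with 4EHP-knockdown under both adjustments (camera adjusted p = 0.755), and 3 and 2 in the double (4 and 3 adjusted over the list alone; camera adjusted p = 0.68). With DHX29-knockdown 0 lymphoid genes were called, and 1 fibroblast or epithelial gene was lower (0 adjusted over the list alone; camera adjusted p = 0.843).

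Hypoxia and glycolysis genes had 4 higher and 15 lower of 29 with DHX29-knockdown (5 and 15 adjusted over the list alone; camera adjusted p = 0.01, adjusted p = 0.518 with an estimated correlation) and 6 and 14 with GIGYF2-knockdown (6 and 15 adjusted over the list alone; camera adjusted p = 0.0468, adjusted p = 0.538 with an estimated correlation). With the offset these counts were 2 and 12, and 3 and 11 (camera adjusted p = 0.00537 and 0.0899). VEGFA, the vascular growth factor, was at 0.546, 0.521 and 0.613 times Control with GIGYF2-, 4EHP- and double knockdown, while EGLN3, a hypoxia-induced hydroxylase, was 1.57-, 1.52- and 1.46-fold higher. Cytokines with AU-rich 3′ UTRs had 4 higher and 3 lower of 10 in the double knockdown under both adjustments (camera adjusted p = 0.907). Immediate early genes had 4 higher and 11 lower of 36 with GIGYF2-knockdown under both adjustments (camera adjusted p = 0.0556), with FOSL1 at 0.725 times Control. Interferon-stimulated genes had 9 higher and 5 lower of 25 (11 and 6 adjusted over the list alone; camera adjusted p = 0.356), with BST2 and DDX58 (RIGI) 1.74- and 1.60-fold higher. Of 21 snoRNA hosts and related non-coding RNAs, 1 was higher and 9 lower with DHX29-knockdown (2 and 10 adjusted over the list alone; camera adjusted p = 0.0808), with LINC00657 (NORAD) 1.47-fold higher and SNHG17 at 0.835 times Control.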
